A study of Glycine max with 24 samples.

How the data were processed

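The authors deposited 1 table of read counts per gene for the 12 leaf libraries and 1 for the 12 root libraries, in whole numbers and not normalized. Per the labels, RNA was extracted with TRIzol and libraries were made with a standard Illumina protocol. HISAT2, a spliced aligner, featureCounts, a read counter, and DESeq2 are named in the submitters' processing notes without role, order or version. The genome build, annotation release, strand setting and plant age are not given in the sources used here. Each table held 57110 rows, of which 57105 named a gene. The other 5 rows, whose names begin with "__" in the form that htseq-count writes, held reads not assigned to a gene and stayed out of library sizes and tests. Reads assigned to genes made up 75.5 to 81.2% of all counted reads in leaf and 70.8 to 78.2% in root. On average, 5.05 to 5.7% of reads per group overlapped no gene, 2.6 to 7.91% were not aligned, and 5.39 to 9.63% had more than 1 alignment. Reads shared between near-identical gene copies, which are frequent in the duplicated soybean genome, therefore count for no gene, and the level of such genes is uncertain, as is that of overlapping or antisense genes.

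IDs were used as the 2 tables give them, with the prefix GLYMA_ in leaf and Glyma. in root, and the same number was taken as the same gene across tissues. A RefSeq gene table for assembly Glycine_max_v4.0 was searched for names, and 0 of the IDs matched it. The 32 gene lists that had been fixed by description could not be filled and were not tested. Of these, 4 also had IDs fixed beforehand, 12 in all, recalled from published work and not checked against an annotation, which is under the minimum of 5 per list for a list test: circadian clock (4), nodule proteins (4), Na+ and K+ transport (2) and abscisic acid synthesis and breakdown (2). These are reported by ID.

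Leaf and root were analysed separately with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with a minimum count of 10, which left 35222 IDs in leaf and 36390 in root holding 99.91 and 99.92% of the gene counts. Libraries were scaled by TMM, with factors of 0.902 to 1.05 in leaf and 0.899 to 1.1 in root. Dispersions were estimated robustly over the 4 groups of a tissue, with no covariate, and quasi-likelihood F tests were made on contrasts of group means. The 5 contrasts per tissue were NaCl against untreated in each genotype, GmNFYA against Jack without and with NaCl, and the interaction. An ID was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F. The tissue by NaCl interaction was fitted in the same way over the 12 Jack libraries of both tissues. Overlaps of calls, all between comparisons that share no library, were tested per direction with a one-sided Fisher's exact test and set beside the number for independent lists. Comparisons within a tissue take their dispersions from the same fit, which can favour the same IDs in both lists. IDs are also not independent units, so that the p-values of overlaps may be too small. Principal components were computed from log2 CPM of the tested IDs.

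The rule for named IDs was fixed before the data were examined: among called IDs with a mean log2 CPM of at least 2 and, except for interactions, no overlap of CPM between the groups, several per direction where descriptions exist and, with no descriptions as here, the 2 with the largest rise and the 2 with the largest fall. CPM values were computed with the TMM factors. A fold against a group with 0 counts was computed against 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio has an exact (Clopper-Pearson) 95% interval. Intervals and bounds cover counting error only.

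No 2 libraries of a group held identical values or counts within sampling noise. In data simulated from the levels of untreated Jack and the real depths and dispersions, 62 of 100 2-fold and 96 of 100 4-fold changes were recovered for NaCl in Jack leaf (35222 IDs), and 81 and 97 of 100 in Jack root (36390 IDs). The interaction recovered 31 of 100 2-fold and 82 of 100 4-fold differences in leaf, and 45 and 93 of 100 in root, so that 2-fold interactions were missed more often than found in both tissues. False calls were 8 of 166 for NaCl in Jack leaf and 12 of 190 in Jack root, 19 of 352 and 29 of 388 in GmNFYA, 16 of 177 and 16 of 184 for genotype with NaCl, and 11 of 124 and 8 of 146 for the interaction. Except for NaCl in Jack leaf, these shares were above the 0.05 aimed at. For untreated genotype in root, where nothing had been changed, 2 IDs were called. Only IDs above a minimum expected count were changed, and far fewer than were called in the real NaCl comparisons. The cutoff on adjusted p depends on that share, so that these rates may differ from those of the real comparisons.

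Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test), RLE size factors, no low-count filter, CPM above 1 in at least 6 libraries, the replicate number as a block, a fit of only the 2 compared groups, and leaving out each library in turn. Overlaps restricted to at least 2-fold changes (except that of NaCl calls between leaf and root in Jack) and libraries thinned to the lowest total (for the leaf interaction and for untreated genotype in root) were added after seeing the data. The authors' own test results were not used here.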

Results

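Gene-level read counts were measured in leaves and roots of soybean (Glycine max). The series compared wild-type plants of the cultivar Jack with a transgenic line labelled as overexpressing GmNFYA, a soybean NF-YA protein. NF-YA is the subunit of the NF-Y transcription factor complex that contacts the CCAAT sequence in promoters. Plants of each genotype were either untreated (0 h) or treated with 150 mM NaCl for 6 h, which gave 8 groups of 3 libraries, 24 libraries in all. The labels name no untreated group at 6 h. If the NaCl groups were harvested 6 h after the untreated groups, NaCl and the elapsed time changed together and cannot be told apart. Reads assigned to genes numbered between 17696429 and 21053889 per leaf library and between 17005570 and 23459341 per root library. The labels give replicate numbers but do not say that replicates came from separate plants, and p-values therefore measure the spread between these samples, which may be technical. No table used here pairs the gene IDs with names or descriptions, so genes are given by ID as in the 2 count tables, with at most 2 that rose and 2 that fell per comparison, besides 12 IDs that were fixed before the data were examined, with functions recalled from published work and not checked against an annotation. Levels are CPM (read counts scaled to a common library size), as mean ± SD over 3 libraries, and changes are log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test. An ID is said to have risen, fallen or differed where its adjusted p was under 0.05.

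The first principal component followed the NaCl treatment in both tissues. It held 51.1% of the variance among leaf libraries and 70% among root libraries, and the second component, with 14.6% and 12%, separated the genotypes. In leaf, the 3 GmNFYA libraries with NaCl had scores of 79.2 to 96.8 on the first component and the 3 Jack libraries with NaCl 43.3 to 63. In root, the untreated GmNFYA libraries had scores of -132 to -120 and the untreated Jack libraries -87 to -78.9. The root libraries with NaCl had scores of 89 to 94.9 in GmNFYA and 112 to 122 in Jack.

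**Figure D1:**
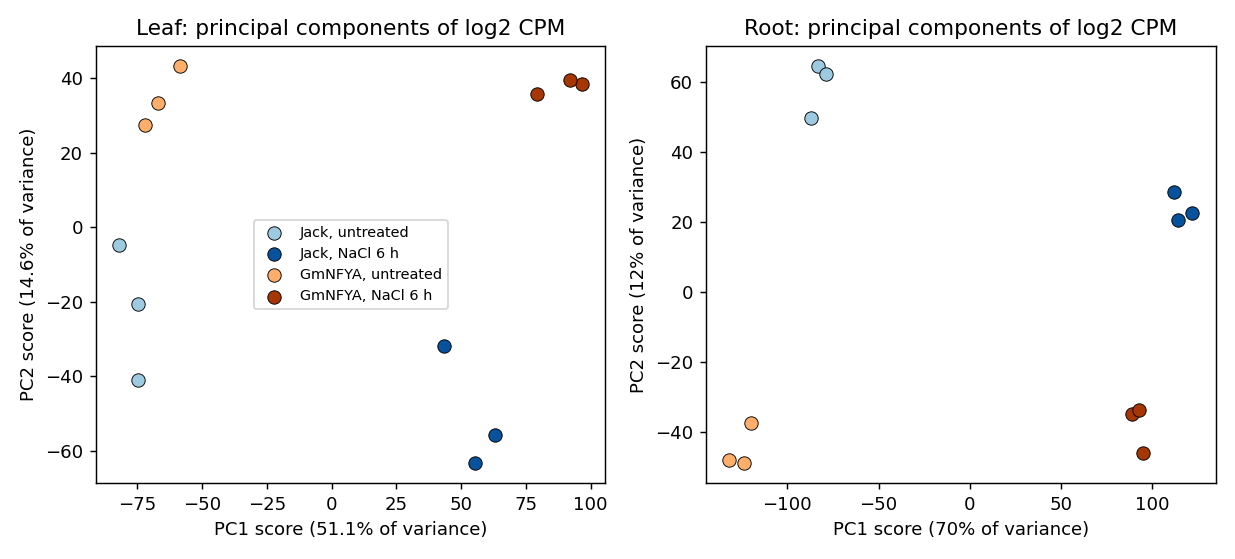
Scores of the 12 leaf libraries (left) and 12 root libraries (right) on the first 2 principal components of log2 CPM, 1 point per library, coloured by group. NaCl and untreated libraries lie on opposite sides of the first component, which held 51.1% of the variance in leaf and 70% in root.

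The labels do not say which GmNFYA gene the transgene carries, and without names no NF-YA transcript could be looked up. ID 02G303800, chosen after its values were seen, stood apart: among the 9 IDs at least 16-fold higher in GmNFYA in all 4 genotype comparisons it had the highest level. Its lowest CPM in any GmNFYA library was 338, against 7.06 for the next of those IDs. In leaf, GLYMA_02G303800 was at 12.9 ± 0.905 CPM in untreated Jack and 636 ± 26.3 CPM in untreated GmNFYA, a 49.5-fold difference (log2 5.63 ± 0.133, adjusted p = 6.46e-11). With NaCl it was at 25.7 ± 1.69 CPM in Jack and 731 ± 68.6 CPM in GmNFYA, a 28.5-fold difference. In root, Glyma.02G303800 was at 1.36 ± 0.376 CPM in untreated Jack and 365 ± 28.5 CPM in untreated GmNFYA, a 266-fold difference (log2 8.06 ± 0.238, adjusted p = 7.04e-11). With NaCl it was at 6.04 ± 2.25 CPM in Jack and 531 ± 24.1 CPM in GmNFYA, 86.3-fold higher. NaCl raised it 2-fold in Jack leaf (adjusted p = 5.18e-05) and 4.48-fold in Jack root (adjusted p = 6.78e-06). In GmNFYA the change was 1.45-fold in root (adjusted p = 0.00867) and 1.15-fold in leaf, where it did not pass the test (adjusted p = 0.165).

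**Figure D2:**
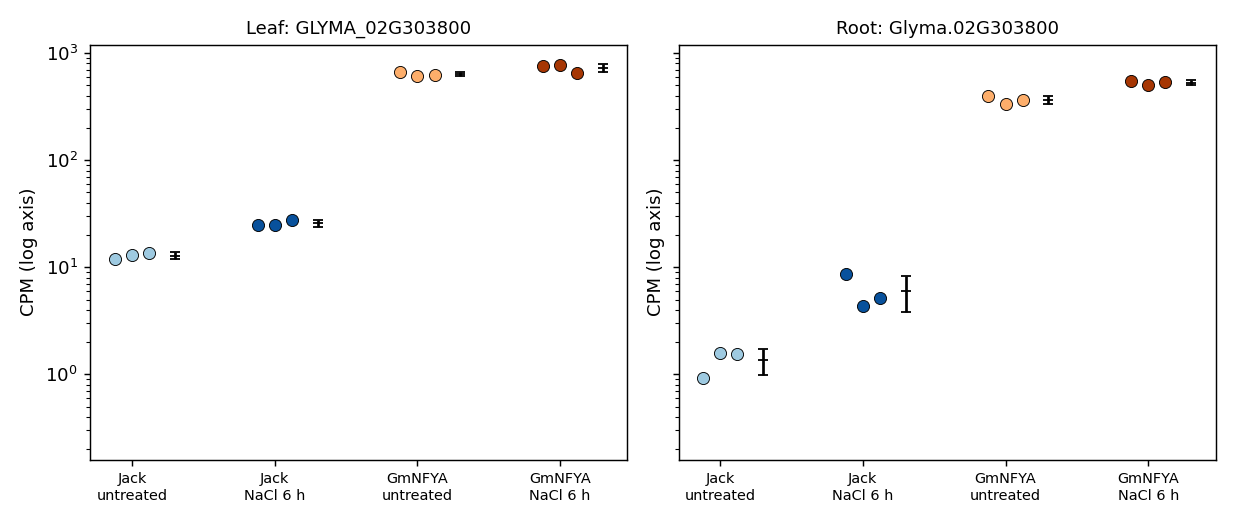
CPM of ID 02G303800 in each library (points, logarithmic axis) with the mean and SD of each group of 3 (bars) in leaf (left) and root (right). All GmNFYA libraries lie between 614 and 780 CPM in leaf and between 338 and 552 CPM in root, and all Jack libraries between 11.9 and 27.6 CPM in leaf and between 0.924 and 8.59 CPM in root.

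NaCl in Jack leaves raised 6283 IDs and lowered 5540 of the 35222 tested, 33.6% of them. GLYMA_03G238800 had 0 counts in the 3 untreated libraries and reached 75.9 ± 64.1 CPM with NaCl, at least 1540-fold higher (against 3 counts over the group; adjusted p = 0.00779). GLYMA_11G180800 likewise went from 0 counts to 23.2 ± 19.2 CPM, at least 468-fold higher (adjusted p = 0.00439). GLYMA_02G028000 fell 22-fold, from 17.6 ± 14.2 to 0.774 ± 1.14 CPM (log2 -4.46 ± 1.09, adjusted p = 0.0114). GLYMA_14G0490002 fell 21.5-fold, from 19.5 ± 5.68 to 0.897 ± 0.444 CPM (log2 -4.43 ± 0.372, adjusted p = 1.36e-05). Among the called IDs, 2335 rose and 1675 fell at least 2-fold, and 370 rose and 43 fell at least 8-fold. With only the 2 compared groups in the fit, the count of calls was 7498 instead of 11823.

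NaCl in GmNFYA leaves raised 6281 IDs and lowered 6422, 36.1% of those tested. GLYMA_03G238800 again had 0 counts without NaCl and rose at least 2390-fold with it (adjusted p = 0.005, and 0.0643 with only the 2 compared groups in the fit). GLYMA_01G021000 rose from 3 counts in the 3 untreated libraries to 184 ± 92.6 CPM, a ratio of 3640 with a 95% counting interval of 1250 to 17700 (adjusted p = 3.27e-05). GLYMA_03G132700 fell 188-fold, from 237 ± 19.5 to 1.26 ± 0.309 CPM (log2 -7.55 ± 0.561, adjusted p = 6.39e-06). GLYMA_14G0490002 fell 58.6-fold, from 19.8 ± 5.4 to 0.333 ± 0.172 CPM (log2 -5.87 ± 0.432, adjusted p = 2.49e-06). At least 2-fold changes were called for 2413 IDs that rose and 2403 that fell. A fit of only the 2 compared groups called 15329 IDs instead of 12703. Of the called IDs, 4213 rose and 3440 fell in both genotypes, 3.76 and 3.41 times the number for independent lists, and 107 changed in opposite directions. The 2 genotypes share no library, but both comparisons take their dispersions from the same fit.

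NaCl in Jack roots raised 10537 IDs and lowered 10158 of the 36390 tested, 56.9% of them. Glyma.01G021000 went from 0 counts to 17.3 ± 1.6 CPM, at least 298-fold higher (adjusted p = 3.84e-06). Glyma.13G363300 went from 0 counts to 16.8 ± 5.25 CPM (adjusted p = 1.54e-07). Glyma.14G054300 fell from 12.8 ± 0.735 CPM to 0 counts, at least 266-fold lower (adjusted p = 7.22e-11). Glyma.16G045100 fell from 5.09 ± 3.99 CPM to 1 count over the 3 libraries, a ratio of 339 with a counting interval of 60.4 to 13400 (adjusted p = 0.000113). At least 2-fold changes were called for 4622 IDs that rose and 4145 that fell. In the untreated Jack root libraries 9.63 ± 0.58% of reads were aligned to more than 1 place, against 6.41 ± 0.27% with NaCl.

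NaCl in GmNFYA roots raised 10410 IDs and lowered 10230, 56.7% of those tested. Glyma.02G088400 rose from 0 counts to 19.6 ± 9.53 CPM, at least 398-fold (adjusted p = 7.31e-05), and Glyma.01G225100 from 0 counts to 12.1 ± 4.55 CPM, at least 245-fold (adjusted p = 1.22e-05). Glyma.16G045100 fell from 28.8 ± 2.32 CPM to 2 counts, a ratio of 967 with a counting interval of 267 to 7990 (adjusted p = 1.81e-06). Glyma.07G033700 fell 140-fold, from 28.3 ± 8.25 to 0.196 ± 0.13 CPM (log2 -7.13 ± 0.319, adjusted p = 1.04e-10). In both genotypes 8138 IDs rose and 7634 fell, 2.7 and 2.67 times the number for independent lists, and 233 changed in opposite directions. Such ratios have a lower ceiling where more IDs are called, as in root, and do not rank the tissues. Across IDs, which are not independent replicates, the log2 fold changes of the genotypes had a Pearson correlation of 0.85 in root and 0.728 in leaf.

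**Figure D3:**
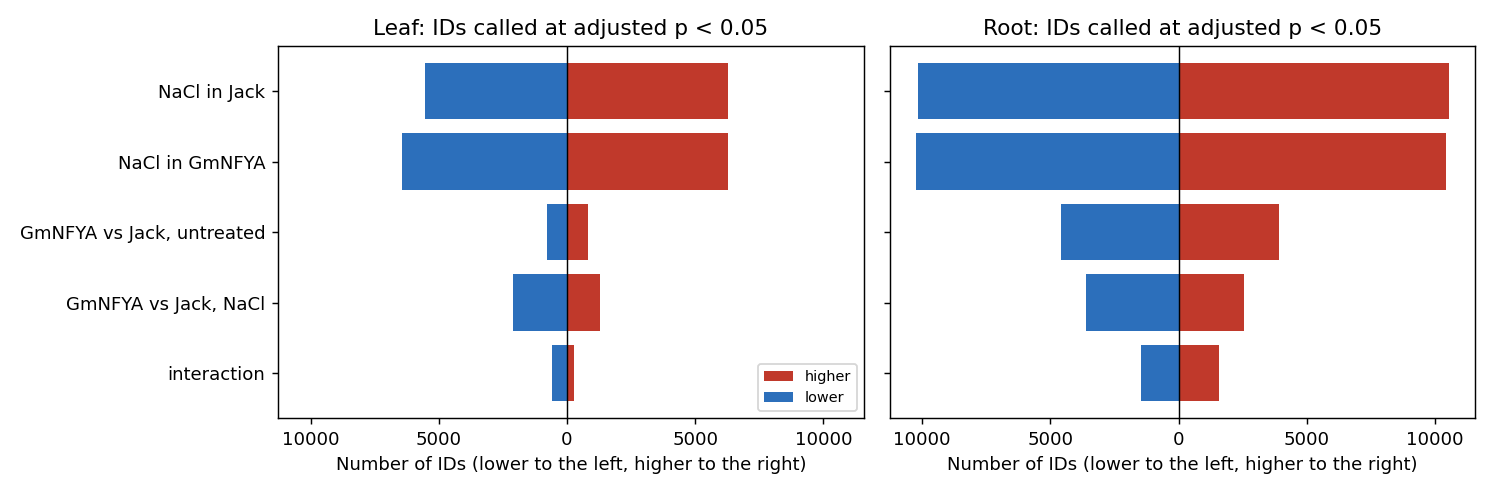
Number of IDs with adjusted p under 0.05 in each comparison, in leaf (left) and root (right), with lower IDs to the left of 0 and higher IDs to the right. For the interaction, higher means a more positive NaCl change in GmNFYA. The NaCl comparisons in root have the longest bars, with 10537 higher and 10158 lower IDs in Jack.

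Untreated GmNFYA leaves differed from untreated Jack leaves in 1590 IDs, 810 higher and 780 lower. GLYMA_02G226700 had 0 counts in Jack and 8.3 ± 0.801 CPM in GmNFYA, at least 168-fold higher (adjusted p = 2.91e-06). GLYMA_18G226500 was 358-fold higher in GmNFYA, at 27.3 ± 0.806 against 0.0719 ± 0.0826 CPM (adjusted p = 2.31e-08). GLYMA_09G208900 had 53 ± 5.57 CPM in Jack and 2 counts in GmNFYA, a ratio of 1450 with a counting interval of 400 to 11900 (adjusted p = 2.74e-08). GLYMA_18G103500 was 641-fold lower in GmNFYA, at 0.0846 ± 0.0532 against 59.4 ± 15.2 CPM (adjusted p = 7.24e-06). The count was 2788 with DESeq2. It was 511, 968 or 547 without GmNFYA replicate 1, 2 or 3, and 760 without Jack replicate 1. The balance of higher and lower IDs turned with Jack replicates, at 688 and 1056 without replicate 2 and 1061 and 700 without replicate 3.

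With NaCl, GmNFYA leaves differed from Jack leaves in 3384 IDs, 1287 higher and 2097 lower. GLYMA_02G226700 was again without counts in Jack and at 9.38 ± 1.02 CPM in GmNFYA, at least 200-fold higher (adjusted p = 3.1e-06). GLYMA_13G042200 had 0 counts in Jack with NaCl and 8.35 ± 1.23 CPM in GmNFYA, at least 179-fold higher (adjusted p = 2.18e-05). GLYMA_18G103500 was 650-fold lower in GmNFYA, at 0.0638 ± 0.11 against 47.1 ± 15.6 CPM (adjusted p = 9.13e-06). GLYMA_09G208900 was 406-fold lower, at 0.0711 ± 0.123 against 29.5 ± 3.86 CPM (adjusted p = 1.08e-07). The count fell to 1712 or 1527 without GmNFYA replicate 1 or 2 and to 2051 without Jack replicate 3. GmNFYA replicate 3 had 9.29% of its reads aligned to more than 1 place, against 5.01 and 4.87% in replicates 1 and 2, and 2274 IDs were called without it. Between the comparisons without and with NaCl, which share no library, 247 IDs were higher and 318 lower in both, 8.35 and 6.85 times the number for independent lists (one-sided Fisher's exact test, p = 6.53e-159 and p = 8.39e-184). Both comparisons take their dispersions from the same fit, and IDs are not independent units, so that these p-values may be too small. That overlap of 565 IDs was 901 with DESeq2 and 365 with only the 2 compared groups in each fit. It was 275, 290 or 373 without GmNFYA replicate 1, GmNFYA replicate 3 or Jack replicate 1, all untreated.

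Untreated GmNFYA roots differed from untreated Jack roots in 8490 IDs, 3910 higher and 4580 lower. Glyma.13G042200 had 0 counts in Jack and 8.98 ± 2.25 CPM in GmNFYA, at least 185-fold higher (adjusted p = 7.69e-07), and Glyma.02G226700 had 0 counts in Jack and 7.22 ± 0.39 CPM in GmNFYA, at least 150-fold higher (adjusted p = 2.09e-08). Glyma.18G245400 had 25.1 ± 1.1 CPM in Jack and 0 counts in GmNFYA, at least 526-fold lower (adjusted p = 2.52e-09). Glyma.03G091700 had 12.2 ± 0.551 CPM in Jack and 0 counts in GmNFYA, at least 254-fold lower (adjusted p = 3.39e-08). Reads aligned to more than 1 place made up 9.63 ± 0.58% in untreated Jack roots and 5.53 ± 0.35% in untreated GmNFYA roots. The count was 5648 without GmNFYA replicate 2.

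With NaCl, GmNFYA roots differed from Jack roots in 6168 IDs, 2567 higher and 3601 lower. Glyma.13G042200 and Glyma.02G226700 again had 0 counts in Jack, with 13.3 ± 2.98 and 11.8 ± 0.361 CPM in GmNFYA, at least 268-fold and 238-fold higher (adjusted p = 1.21e-06 and 1.65e-08). Glyma.18G245400 and Glyma.03G091700 again had 0 counts in GmNFYA, with 41.9 ± 7.71 and 5.34 ± 1.26 CPM in Jack, at least 772-fold and 101-fold lower (adjusted p = 1.28e-09 and 8.84e-07). The count was 3868, 3886 or 3918 without GmNFYA replicate 1, 2 or 3, and 3932 without Jack replicate 2. Between the comparisons without and with NaCl, 863 IDs were higher and 1360 lower in both, 3.13 and 3 times the number for independent lists (p = 4.87e-235 by one-sided Fisher's exact test for higher IDs). These comparisons also take their dispersions from the same fit. Untreated leaf and root shared 199 IDs higher and 214 lower in GmNFYA, 2.54 and 2.5 times the number for independent lists (p = 2.27e-36 and p = 5.86e-39, Fisher's exact test), while 163 differed in opposite directions. That overlap of 413 IDs was 719 with DESeq2. It was 180, 191 or 256 without leaf GmNFYA replicate 1, leaf GmNFYA replicate 3 or leaf Jack replicate 1, all untreated.

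The interaction asked whether the NaCl change differed between the genotypes. In leaf it was called for 863 IDs, with a more positive change in GmNFYA for 275 and a more negative change for 588. GLYMA_03G069400 rose from 0.579 ± 0.203 to 2.35 ± 0.694 CPM in Jack and from 0.369 ± 0.112 to 18.6 ± 4.17 CPM in GmNFYA (log2 difference 3.64 ± 0.491, adjusted p = 0.00459). GLYMA_07G052100 rose from 1.19 ± 0.374 to 9.31 ± 5.23 CPM in Jack and from 0.576 ± 0.0986 to 47.1 ± 13.2 CPM in GmNFYA (log2 difference 3.38 ± 0.755, adjusted p = 0.0464), a call lost without the low-count filter (adjusted p = 0.0762) and with any 1 of 9 libraries left out. The neighbouring IDs GLYMA_14G176300 and GLYMA_14G176400 fell from 47.1 ± 8.96 to 0.987 ± 0.335 CPM and from 169 ± 19.4 to 6.24 ± 3.41 CPM in GmNFYA. In Jack they were at 6.16 ± 4.64 and 28.4 ± 17.2 CPM without NaCl and at 15.4 ± 12.4 and 62.2 ± 44.4 CPM with it (log2 differences -6.89 ± 1.1 and -5.89 ± 0.984, adjusted p = 0.0164 and 0.0186). Their calls were lost without GmNFYA NaCl replicate 1 (adjusted p = 0.0535) for the first and without untreated GmNFYA replicate 2 or Jack replicate 1 (adjusted p = 0.0502 and 0.0541) for the other. The count was 1876 with DESeq2. Without untreated GmNFYA replicate 1, 2 or 3 it was 462, 242 or 229, without GmNFYA NaCl replicate 1 or 2 it was 322 or 307, without untreated Jack replicate 1 or 3 it was 343 or 1339, and without Jack NaCl replicate 3 it was 561. Without untreated Jack replicate 2, 497 IDs had a more positive and 608 a more negative change.

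In root the interaction was called for 3018 IDs, with a more positive change in GmNFYA for 1557 and a more negative one for 1461. That balance turned with DESeq2 (1859 and 1875) and without Jack NaCl replicate 1 (1972 and 2240). The interaction rests in part on the untreated Jack root libraries, in which 9.63 ± 0.58% of reads were aligned to more than 1 place. Glyma.07G193500 rose from 0 counts to 5.29 ± 1.05 CPM in GmNFYA and was at 3.54 ± 1.51 and 9.05 ± 2.62 CPM in Jack (fitted log2 difference 8.37 ± 1.11, adjusted p = 0.000875). Glyma.01G225100 rose from 0 counts to 12.1 ± 4.55 CPM in GmNFYA and from 2.15 ± 0.406 to 22.7 ± 9.23 CPM in Jack (fitted log2 difference 7.54 ± 1.64, adjusted p = 0.0253), a call lost without the low-count filter (adjusted p = 0.051) or with any 1 of 5 libraries left out. Glyma.14G167800 rose from 0 counts to 13.8 ± 5.94 CPM in Jack and from 0.714 ± 0.249 to 4.81 ± 0.865 CPM in GmNFYA (fitted log2 difference -8.35 ± 1.4, adjusted p = 0.00481). Glyma.17G041200 rose from 0.858 ± 0.238 to 43.5 ± 24.3 CPM in Jack and from 4.56 ± 1.41 to 10.3 ± 1.2 CPM in GmNFYA (log2 difference -4.45 ± 0.795, adjusted p = 0.00919). Where a group had 0 counts, the size of the fitted difference depends on the prior count.

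Leaf and root responses to NaCl were compared in Jack, first by overlap and then by a test of the difference. Of 32699 IDs tested in both tissues, 3728 rose and 2486 fell in both, 2.1 and 1.84 times the number for independent lists (p = 1.08e-306 for falls, one-sided Fisher's exact test), and 1193 changed in opposite directions. Across these IDs, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.501. With only the 2 compared groups in each fit, 4004 IDs instead of 6214 changed the same way in both tissues. In GmNFYA, 3188 rose and 2404 fell in both tissues, 1.85 and 1.53 times the number for independent lists, and 2023 changed in opposite directions. The tissue by NaCl interaction in Jack was called for 7875 of 37920 IDs, with a more positive change in root for 4056 and a more negative one for 3819. That balance depended on the scaling, with 4695 and 3082 under RLE size factors and 5432 and 3671 with DESeq2. In 1190 of the called IDs, each also called in both tissues, the tissues changed in opposite directions, with 724 rising in root and falling in leaf and 466 the reverse. Glyma.06G302200 rose from 0 counts to 5.39 ± 2 CPM in root and was at 8.6 ± 7.8 and 6.12 ± 1.59 CPM in leaf (adjusted p = 0.00659). Glyma.18G210900 rose from 0 counts to 5.96 ± 2.74 CPM in root and was at 16.1 ± 13.1 and 15.5 ± 10.2 CPM in leaf (adjusted p = 0.0225, a call lost without the low-count filter, adjusted p = 0.0618, or without root Jack NaCl replicate 3, adjusted p = 0.0502). Glyma.03G254300 fell from 31.6 ± 5.53 to 0.761 ± 0.202 CPM in root and had 0 and 5 counts in leaf (adjusted p = 0.000906). Glyma.15G021800 fell from 69 ± 23.5 to 0.707 ± 0.108 CPM in root and rose from 1.86 ± 0.601 to 10.9 ± 4.35 CPM in leaf (adjusted p = 3.84e-06).

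The 12 IDs fixed beforehand fall into 4 groups, whose functions were recalled from published work and not checked against an annotation. Both IDs of abscisic acid synthesis and breakdown, the hormone pathway of drought and salt responses, rose with NaCl in both tissues and genotypes. In leaf, GLYMA_15G250100 rose from 8.49 ± 3.25 to 75.1 ± 30.5 CPM in Jack (log2 3.15 ± 0.36, adjusted p = 0.000133) and from 6.66 ± 1.95 to 261 ± 14.5 CPM in GmNFYA (log2 5.29 ± 0.39, adjusted p = 4.68e-06). The difference between these changes was 2.14 ± 0.49 on the log2 scale (adjusted p = 0.0484), a call lost without the low-count filter (adjusted p = 0.0794) and with any 1 of 9 libraries left out. GLYMA_08G176300 rose from 0.615 ± 0.131 to 7.39 ± 4.47 CPM in Jack and from 0.556 ± 0.27 to 22.5 ± 0.699 CPM in GmNFYA (interaction adjusted p = 0.281). In root, Glyma.15G250100 rose from 0.857 ± 0.207 to 48.2 ± 15.1 CPM in Jack and from 2.33 ± 0.0838 to 103 ± 11 CPM in GmNFYA (interaction adjusted p = 0.667). Glyma.08G176300 rose from 0.739 ± 0.241 to 7.32 ± 2.58 CPM in Jack and from 0.233 ± 0.144 to 13.5 ± 3.4 CPM in GmNFYA, and the changes differed (log2 2.45 ± 0.65, adjusted p = 0.0319), a call lost with any 1 of 5 libraries left out. With NaCl, both IDs were higher in GmNFYA than in Jack in leaf (log2 1.61 ± 0.35 and 1.8 ± 0.33) and in root (0.87 ± 0.26 and 1.09 ± 0.17). Without NaCl, Glyma.15G250100 was already higher in GmNFYA root (log2 1.42 ± 0.34, adjusted p = 0.00968), while Glyma.08G176300 (log2 -1.57 ± 0.59, adjusted p = 0.0706) and both IDs in leaf (adjusted p = 0.953 and 0.662) did not pass the test. Untreated Glyma.08G176300 did pass as lower in GmNFYA root with DESeq2 (adjusted p = 0.011) and with only the 2 compared groups in the fit (adjusted p = 0.039). For 08G176300 the genotype call with NaCl was lost in leaf (adjusted p = 0.0727) and in root (adjusted p = 0.0819) with only the 2 compared groups in the fit, and with any 1 of 2 libraries left out in leaf or any 1 of 4 in root.

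Of the 2 IDs of Na+ and K+ transport, Glyma.03G171600 fell in root with NaCl from 49.1 ± 1.61 to 4.79 ± 0.191 CPM in Jack (log2 -3.35 ± 0.12, adjusted p = 9.7e-12) and from 53.4 ± 1.06 to 3.17 ± 0.87 CPM in GmNFYA (log2 -4.07 ± 0.13, adjusted p = 1.47e-12). Its fall was larger in GmNFYA by 0.72 on the log2 scale (interaction -0.72 ± 0.18, adjusted p = 0.0211), a call lost without GmNFYA NaCl replicate 2 (adjusted p = 0.0684) or 3 (adjusted p = 0.0613). With NaCl it was lower in GmNFYA than in Jack (log2 -0.60 ± 0.15, adjusted p = 0.0121), a call lost with only the 2 compared groups in the fit (0.0936) and without GmNFYA NaCl replicate 2 (0.056) or 3 (0.0597). In leaf GLYMA_03G171600 stayed at 1.03 to 3.19 CPM on average and fell with NaCl in GmNFYA (log2 -1.42 ± 0.26, adjusted p = 0.000906) and in Jack (log2 -0.83 ± 0.27, adjusted p = 0.0315, 0.0924 with only the 2 compared groups in the fit, and 0.0517 to 0.107 with any 1 of 4 libraries left out). Glyma.08G092000 rose in root in Jack from 73.9 ± 6.47 to 101 ± 9.1 CPM (log2 0.45 ± 0.087, adjusted p = 0.000374) and in GmNFYA from 74.6 ± 1.52 to 88.1 ± 4.01 CPM (log2 0.24 ± 0.086, adjusted p = 0.0259, a call lost with any 1 of 4 libraries left out). In leaf it was at 11.1 to 12.9 CPM on average in every group and passed no test.

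Of the 4 circadian clock IDs, 1 fell with NaCl in Jack leaf and 0 in GmNFYA leaf, and 1 fell in Jack root and 3 in GmNFYA root. The leaf call, GLYMA_07G048500, was at 217 ± 8.01 CPM without and 168 ± 32 CPM with NaCl (log2 -0.37 ± 0.14, adjusted p = 0.0492). Adjusted over the list alone, it did not pass (0.0657). That call was lost without the low-count filter (0.0593), with only the 2 compared groups in the fit (0.148), with any 1 of the 3 untreated Jack libraries left out (0.12, 0.0523 and 0.0944 without replicate 1, 2 and 3) and without Jack NaCl replicate 1 (log2 -0.22, 0.15). Glyma.03G261800 fell in GmNFYA root from 10.7 ± 1.16 to 4.7 ± 0.859 CPM (log2 -1.18 ± 0.16, adjusted p = 9.34e-06) and was at 15.6 ± 2.07 and 13.2 ± 1.56 CPM in Jack (interaction -0.95 ± 0.21, adjusted p = 0.0118). In leaf the same gene, GLYMA_03G261800, was lower in GmNFYA than in Jack without NaCl, at 157 ± 9.95 against 289 ± 14.5 CPM (log2 -0.88 ± 0.19, adjusted p = 0.021, a call lost with any 1 of 4 libraries left out), and with NaCl, at 160 ± 6.46 against 298 ± 100 CPM (log2 -0.89 ± 0.19, adjusted p = 0.0117, and 0.0712 with only the 2 compared groups in the fit or 0.0568 without GmNFYA NaCl replicate 2). In root, 2 of the 4 clock IDs were lower in GmNFYA without and with NaCl. Glyma.03G261800 had log2 differences of -0.55 ± 0.15 (adjusted p = 0.0128, 0.0587 without GmNFYA untreated replicate 2 and 0.0637 without Jack untreated replicate 1) and -1.49 ± 0.16 (adjusted p = 1.92e-05). Glyma.19G260900 had -0.68 ± 0.22 (adjusted p = 0.0399, and 0.12 to 0.151 with any 1 of 4 libraries left out) and -0.98 ± 0.23 (adjusted p = 0.0117, and 0.0521 without GmNFYA NaCl replicate 2). In untreated leaf 1 of the 4 clock IDs was lower in GmNFYA over all IDs tested and 4 were when adjusted over the list alone. In root, the 3 calls in GmNFYA were those of Glyma.03G261800, Glyma.19G260900 (log2 -0.61, adjusted p = 0.0387) and Glyma.07G048500 (log2 -0.36, adjusted p = 0.0174). The call of Glyma.19G260900 was lost with any 1 of 5 libraries left out (adjusted p up to 0.155), and that of Glyma.07G048500 without GmNFYA NaCl replicate 2 (log2 -0.24, adjusted p = 0.101). Glyma.07G048500 was also the call in Jack root (log2 -0.40), lost without Jack NaCl replicate 3 (adjusted p = 0.0547). The 4 nodule protein IDs had too few counts to be tested in either tissue. The other root groups had 0 or 1 counts at each of them, and in the untreated GmNFYA group all counts came from replicate 3, with 5, 25, 77 and 33.

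**Figure D4:**
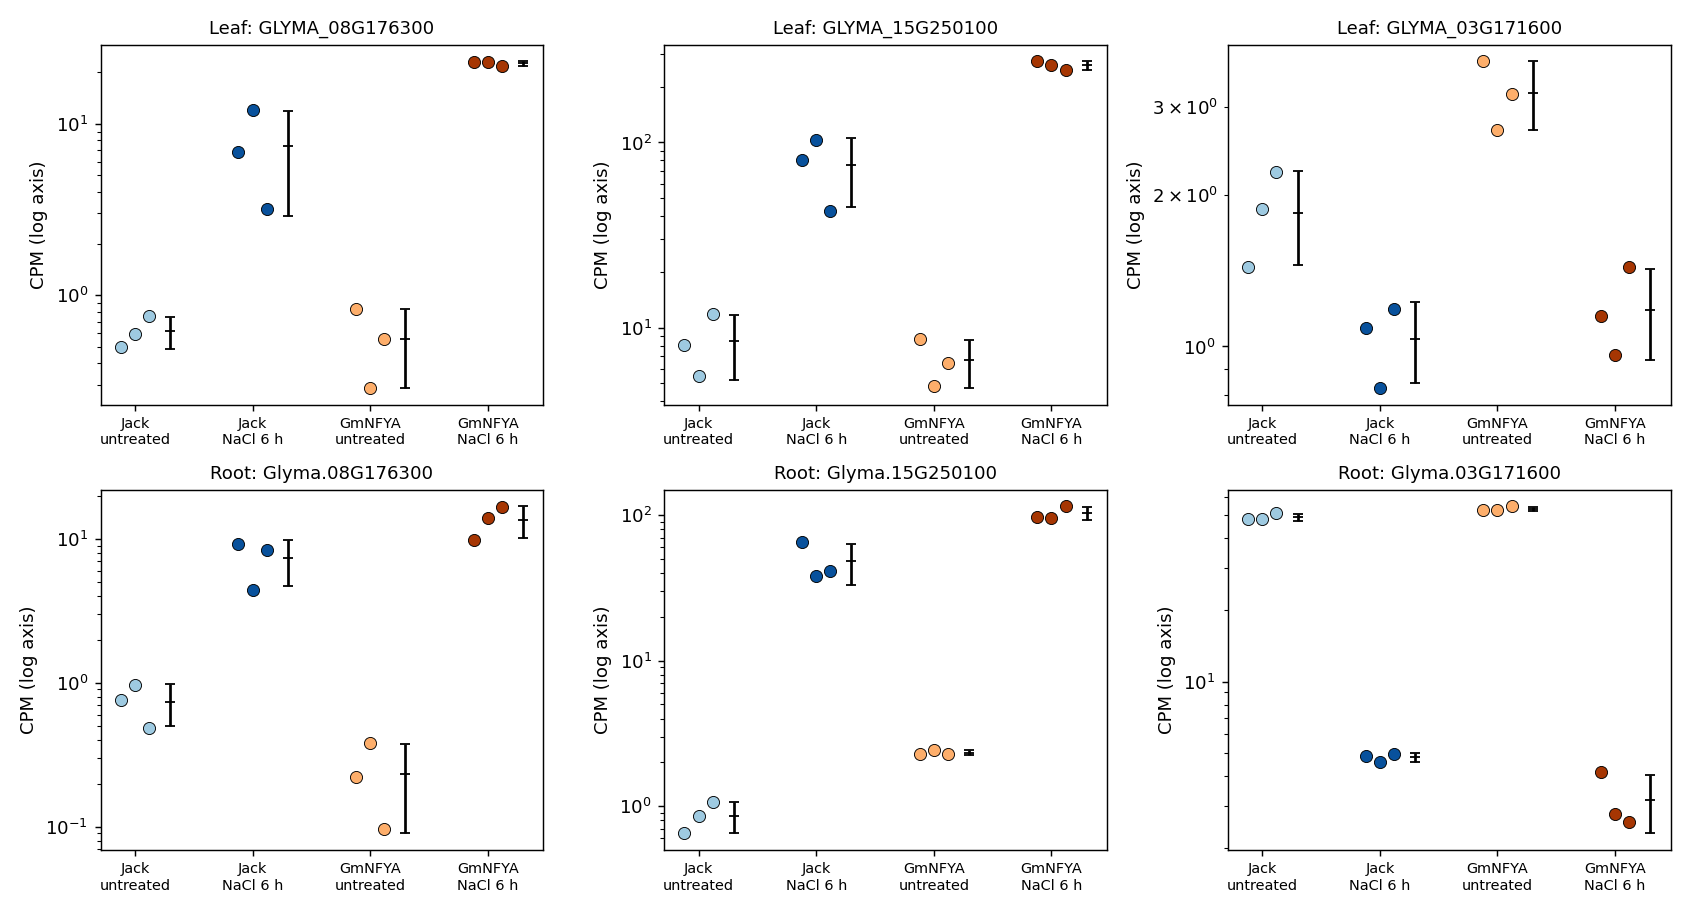
CPM of the 2 IDs of abscisic acid synthesis and breakdown and of 1 ID of Na+ and K+ transport in each library (points, logarithmic axes), with the mean and SD of each group of 3 (bars), in leaf (top) and root (bottom). Root Glyma.03G171600 has means of 49.1 and 53.4 CPM in untreated libraries and means of 4.79 and 3.17 CPM with NaCl.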

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

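The regroupings were fixed before their results were seen, while thinning to the lowest total of gene counts and all tests of slopes, left-out libraries included, were chosen only after the result was seen.

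The NaCl change differed between genotypes for 863 IDs in leaf and 3018 in root, and between tissues in Jack for 7875. By the rule fixed beforehand, the IDs named for the interaction in leaf were GLYMA_03G069400 (log2 difference 3.64), GLYMA_07G052100 (3.38), GLYMA_14G176300 (-6.89) and GLYMA_14G176400 (-5.89). In root they were Glyma.07G193500 (8.37), Glyma.01G225100 (7.54), Glyma.14G167800 (-8.35) and Glyma.17G041200 (-4.45). Glyma.07G193500 and Glyma.01G225100 had 0 counts in untreated GmNFYA and Glyma.14G167800 in untreated Jack, so that the sizes of their differences depend on the prior count. Among the IDs fixed beforehand the interaction was called for GLYMA_15G250100 in leaf (2.14) and for Glyma.08G176300 (2.45), Glyma.03G261800 (-0.95) and Glyma.03G171600 (-0.72) in root. ID 02G303800, chosen after its values were seen, had a smaller log2 change with NaCl in GmNFYA than in Jack in leaf (GLYMA_02G303800, -0.80, adjusted p = 0.0208, a call lost with any 1 of 6 libraries left out) and in root (Glyma.02G303800, -1.62, adjusted p = 0.0048). On the CPM scale its mean went up more in GmNFYA. In leaf it went from 636 to 731 CPM, against 12.9 to 25.7 in Jack. In root it went from 365 to 531 CPM, against 1.36 to 6.04 in Jack. The root minus leaf differences in Jack were 10.25 for Glyma.06G302200, 9.95 for Glyma.18G210900, -9.26 for Glyma.03G254300 and -9.15 for Glyma.15G021800. Glyma.06G302200 and Glyma.18G210900 had 0 counts in untreated root and Glyma.03G254300 in untreated leaf, so that the sizes of these differences also depend on the prior count.

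In data outside the tested IDs, the leaf GmNFYA NaCl replicate 3 had 9.29% of its reads aligned to more than 1 place, against 5.01 and 4.87% in replicates 1 and 2. The 4 nodule protein IDs held 140 reads in root GmNFYA untreated replicate 3 and 0 reads in the 6 Jack root libraries.

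Genotype labels were regrouped within treatment for the genotype by NaCl interactions, and treatment labels within tissue for the tissue interaction, with 100 regroupings each, the real one included. As many IDs as in the real grouping were called by 2 of 100 in leaf, 2 of 100 in root and 4 of 100 for the tissues. These counts do not decide whether chance can be excluded. Of the 100, 81 mixed the labels in both treatments (or tissues), which puts the main difference into the spread within groups, and they called at most 0 IDs with edgeR in leaf and root and 2 for the tissues. The highest other value came from the regrouping that exchanges the labels of 1 treatment (or tissue) completely, with 4004 IDs in leaf against 863, 11028 in root against 3018 and 17422 for the tissues against 7875, a structure of the samples. The highest values without it were 558, 2954 and 9503. For the 8 comparisons of 2 groups, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split alone (1 of 10 in each) gave 11823 and 12703 IDs for NaCl in Jack and GmNFYA leaf, 20695 and 20640 in root, 1590 and 3384 for genotype without and with NaCl in leaf, and 8490 and 6168 in root. The highest other split gave 183 IDs for NaCl in Jack leaf and 0, with edgeR at adjusted p under 0.05, for the other 7.

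In leaf, where the NaCl change was larger in GmNFYA, 666 of the 863 interaction calls (77.2%) had the sign of the average NaCl change of the 2 genotypes, and the interaction had a slope of 0.137 on that average across 35222 IDs, which are not independent replicates (-0.039 is expected from unequal spread within the groups). A difference in total gene counts is argued against: with every library thinned to 17696429 counts, 76.6% of the calls had that sign. The size rests in part on 1 library, since the slope was 0.0589 without Jack NaCl replicate 1, less than 50% of its value, while it stayed above 0 without any of the 12 libraries. An effect of the line shared by both tissues is consistent with the slope of 0.0732 in root, but the support is thin: the root value is the slope of -0.094 with NaCl less that of -0.167 without, and so rests on untreated Jack roots, whose library quality stays open, while leaf had 0.185 with NaCl, and the interactions of the 2 tissues had a Pearson correlation of 0.0486 across IDs. It remains a hypothesis beside unequal growth or handling of the groups, which was not tested.

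In root, untreated GmNFYA differed from untreated Jack against the direction of the NaCl change. The 36390 IDs had a slope of -0.167 on the average NaCl change, with a Pearson correlation of -0.294. A slope of 0.00014 is expected from unequal spread within the groups. A difference in total gene counts is argued against by a slope of -0.169 with every library thinned to 17005570 counts, and 1 library out of place by a slope of -0.153, the nearest to 0 with 1 library left out. Untreated Jack roots also stood apart in their reads, with 9.63% aligned to more than 1 place against 5.48 to 6.41% in the other root groups and 71.4% assigned to genes against 75.5 to 77.7%, so that RNA or library quality stays open and was not tested. With NaCl, GmNFYA roots also differed from Jack roots against that direction, with a slope of -0.094 (-0.115 to -0.0805 with 1 library left out). That genotype difference uses no untreated library, although the average NaCl change does. It argues against the state of untreated Jack roots as the whole cause. Untreated Jack roots may still have been partway to the NaCl state from growth or handling, or the line may differ from Jack in that direction. These cannot be told apart by the slope of -0.167, because the state of the plants and of their libraries is confounded with genotype.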

How the results depend on the processing

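Restrictions of overlaps to at least 2-fold changes, except in Jack between leaf and root, and thinning were chosen after seeing the data. RLE scaling, dropping the low-count filter, the stricter filter and thinning left each count of calls and overlap they were run on within 1.5 times its value. Thinning gave 8202 calls for untreated genotype in root and 854 for the leaf interaction. The stricter filter was not run for the tissue interaction. Among the 88 ID results past the threshold, 0 changed sign under any alternative, while 14 of the others did. Many of the 88 were picked for large changes, and every alternative reuses the same libraries, so that this contrast does not test the results. With DESeq2, calls rose from 1590 to 2788 for untreated genotype in leaf and from 863 to 1876 for the leaf interaction, and overlaps from 565 to 901 for leaf genotype without and with NaCl and from 413 to 719 for untreated genotype in leaf and root; the cause was not tested. With only the 2 compared groups, NaCl in Jack leaf fell from 11823 to 7498, the Jack leaf and root overlap from 6214 to 4004 and the leaf genotype overlap from 565 to 365, while NaCl in GmNFYA leaf rose from 12703 to 15329 and its leaf and root overlap from 5592 to 6617. Leaf libraries of the same group differed more in Jack (chi-square per degree of freedom 11.7 to 31.8 per pair) than in GmNFYA (3.42 to 14), with overlapping ranges. The main fit shares its dispersions over all groups of a tissue. Whether this caused the shifts was not tested. Restricted to at least 2-fold changes, overlaps were 1822 for NaCl between leaf and root in Jack, 1715 in GmNFYA, 2297 between genotypes in leaf, 6586 in root, 240 and 430 for genotype without and with NaCl in leaf and root, and 134 for untreated genotype between tissues, with fewer IDs by construction.

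Leaving out 1 library gave 511 to 1761 calls for untreated genotype in leaf, with 511, 968 and 547 without GmNFYA replicates 1, 2 and 3 and 760 without Jack replicate 1. With NaCl it gave 1527 to 3307, with 1712 and 1527 without GmNFYA replicates 1 and 2 and 2051 without Jack replicate 3. The leaf interaction ranged from 229 to 1339: 462, 242 and 229 without untreated GmNFYA replicates 1, 2 and 3, 322 and 307 without GmNFYA NaCl replicates 1 and 2, 343 and 1339 without untreated Jack replicates 1 and 3, and 561 without Jack NaCl replicate 3. In root it gave 5648 (without GmNFYA replicate 2) to 8622 for untreated genotype. With NaCl it gave 3868 to 6214 in root, with 3868, 3886 and 3918 without GmNFYA replicates 1, 2 and 3 and 3932 without Jack replicate 2. The leaf genotype overlap ranged from 275 to 535, with 275 and 290 without untreated GmNFYA replicates 1 and 3 and 373 without untreated Jack replicate 1. The untreated overlap between tissues ranged from 180 to 447, with 180 and 191 without the same 2 leaf GmNFYA libraries and 256 without leaf Jack replicate 1. The other counts in these runs stayed within 1.5 times.

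Replicate numbers did not meet the bar set for pairing, a correlation over 0.1 in every pair. Correlations of deviations between same-numbered samples were -0.0654 to 0.292 in leaf (4 of 18 pairs over 0.1). In root they were -0.157 to 0.132 (1 of 18). The mean correlation was higher with the own number than with other numbers for 12 of 12 leaf and 6 of 12 root samples. In leaf, same-numbered pairs had a mean of 0.066 and other pairs -0.0332, so that structure shared by replicate number is not excluded there. The replicate block gave 1385 calls for the leaf interaction and moved no other count by over 1.5 times. Under the block the adjusted p passed 0.05 for GLYMA_15G250100 (leaf interaction, 0.0636), Glyma.08G176300 (root interaction, 0.0538, and genotype with NaCl, 0.06) and Glyma.19G260900 (untreated genotype in root, 0.0521), and for no other ID result. Of 88 ID results past the threshold, 24 lost it under some alternative, and 6 others gained it.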

Other observations

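All of the tests in this part were chosen after the result was seen.

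The interaction calls were sorted by the sign of the NaCl change averaged over Jack and GmNFYA. That average did not have to pass a test, and the genotypes could change in opposite directions. In leaf, the change was more negative in GmNFYA for 436 IDs with a negative average and more positive for 230 with a positive average. It was more negative for 152 with a positive average and more positive for 45 with a negative average. In root, the change was more positive in GmNFYA for 1089 IDs with a positive average and more negative for 697 with a negative average. It was more negative for 764 with a positive average and more positive for 468 with a negative average. Among the 32699 IDs tested in both tissues, 134 had an interaction in both, against 64.9 for independent lists, 93 of them in the same direction and 41 in opposite directions. Across all of these IDs the interaction in leaf and in root had a Pearson correlation of 0.0486.

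A set of 153 IDs differed the same way in all 4 genotype comparisons, 63 higher and 90 lower in GmNFYA. All-or-none differences, with at most 3 counts over the 6 libraries of 1 genotype and a mean of at least 1 CPM in the other, were found for 4 IDs seen only in GmNFYA and 8 seen only in Jack in both tissues, and 0 IDs were opposite between tissues. IDs of the soybean annotation carry the chromosome number and are numbered in order along it, and 152 of the 153 could be placed. Chromosomes 18 and 13 held 22 and 19 of them, 14.5 and 12.5%, against 4.87 and 7.01% of the IDs tested in both tissues. There were 6 runs of at least 5 IDs with no gap over 50 places, such as 8 IDs between Glyma.18G075200 and Glyma.18G087000 and 6 between Glyma.03G065700 and Glyma.03G070300.

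These IDs lay near each other: 48.7% of the 152 had another of the set 6 to 50 places away, against a median of 21.7% and a highest value of 35.5% in 1000 random draws of as many tested IDs. Tandem copies within 5 places are argued against as the whole cause by the same 48.7%, which counts no neighbour within 5 places. Members of such groups were not merged (18.4% of the 152 had another within 1 to 5 places), and longer arrays were not left out. For an overexpressed factor, the share argues only against targets placed at random among the tested IDs. Targets that lie near each other stay open. General coregulation of neighbours stays open. Draws from 3420 IDs that changed the same way in all 4 NaCl comparisons reached at most 36.8%. Each draw kept only 152 of the 3420, which breaks up small groups of neighbours, so that this share does not decide the question. A candidate explanation is that the line and the Jack plants carry different versions of some chromosome segments, which the share of 48.7% fits. The all-or-none IDs, which such segments would also produce, do not decide on it. Of the 11 that were placed, 36.4% had another 6 to 50 places away, against a highest random draw of 45.5%. Only the highest draw was kept for these few IDs, so how rarely draws reach 36.4% is not known. The explanation by segments stays a hypothesis, because the pattern was first noticed among the same IDs, and sequence, wider gene clusters and effects of the transgene on its surroundings were not analysed here.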
